A study of Mus musculus with 7 samples.

How the data were processed

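RNA was sequenced from germinal center B cells sorted from the spleens of mice carrying a deleted Hdac7 gene and of control mice. Sorting selected B220-positive cells that also carried FAS and GL7, markers of germinal center B cells. Per the labels' protocols, the knockout used a floxed Hdac7 allele and a Cre recombinase driven by the promoter of the Cgamma-1 immunoglobulin gene, libraries were made by a low-input method, and read pairs of 100 bp were generated. The titles give 4 knockout samples (KO1 to KO4) and 3 control samples (WT1, WT2 and WT4). The labels do not say that each sample came from a separate animal, or whether the control mice carried the Cre. All p-values therefore measure the spread between these samples, part of which may be technical. One label field calls the cells of every sample wild-type, the KO samples included, so the groups were taken from the titles, which match the genotype field. No label gives a sequencing batch, an age or a sex.

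A single table of the whole series was used. The submitters' processing notes name FastQC, STAR 2.7.0a, HTSeq 0.10.0 and DESeq2, without their settings or order, and the genome builds GRCm38 and mm10. The gene identifiers carry the prefix of a C57BL/6NJ strain annotation instead, so the annotation that was counted is taken from the identifiers and its version is not given in the sources used here. For each gene the deposited signal is a read count divided by a size factor for the sample, by the authors, and the deposited mean is the average of the 7 samples. The same table gives the authors' own comparison of KO with WT: a log2 fold change and its standard error on the log2 scale, a test score (the fold change divided by its standard error), a p-value and an adjusted p-value. Whether counting used strand, and how reads of near-identical or overlapping genes were assigned, is not given in the sources used here.

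The table had 41838 rows. Of these, 742 repeated the identifier and values of another row, for 701 identifiers, and were dropped, which left 41096 genes. In every sample, 100% of the values above 0 were whole multiples of a single step, within a tolerance of 0.001 reads, so whole reads were recovered exactly. The recovered totals were 14681494 to 18642230 reads per sample, or 29.4% to 37.3% of the number of read pairs that the labels state for each. These totals cover reads assigned to genes in the table. Of the 41096 genes, 18105 had no read in any sample. A DESeq2 (1.42.0) refit of the recovered reads matched the authors' deposited log2 fold changes to within 7.45e-07.

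The table pairs no identifier with a gene symbol, and 0 identifiers of its kind were present in the symbol tables used here. Genes are therefore given by identifier, without symbol, position or function, and only 2 higher and 2 lower genes are named. Parts of the plan fixed before the data were examined were not run for this reason: the level of Hdac7 in each sample as a check of the labels, the tests of fixed lists of pathway genes and of markers of other cell types, the shares of heavy-chain isotypes, and an alternative without immunoglobulin genes. The naming rule, fixed beforehand, asked for Hdac7, for the genes with the largest changes and the 5 with the smallest p in each direction, and for members of the fixed lists. It took genes past the threshold with a mean of at least 1 CPM and no overlap between KO and WT samples, and the 2 with the smallest p in each direction were kept from it.

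The plan foresaw edgeR's quasi-likelihood test for raw counts and limma on log2(value + 1) for counts divided by size factors. The second case applied. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), two-sided, without covariates, on all 7 samples, with a trend of variance on mean level (limma-trend) and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which can understate or overstate the change of genes with few reads against a fold fitted to counts. The plan did not state whether to fit the trend. It was chosen after the calls with and without it were seen, because the spread of log counts depends on their level. Genes with too few reads were removed by filterByExpr of edgeR (4.0.16) on the recovered reads, which left 14255 genes holding at least 99.8% of the reads of each sample. The alternatives were edgeR, DESeq2 and limma-voom on the recovered reads, other scalings, pseudocounts and filters, leaving out each sample, the title number as a block, and splits of the samples as a term.

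The tests were checked on 3 simulated data sets of 14255 genes, in which 200 genes changed. Means, depths and the spread of each gene were estimated from this comparison. Genes were drawn independently, without differences between samples that many genes share. Recovery also depends on how many genes change, so these rates hold for the simulated setting and may differ in the real data. Limma-trend recovered 79.8% of the genes changed 4-fold, 51.2% of those changed 2-fold and 11.4% of those changed 1.5-fold, with a mean of 9.33 false calls among 104.0. DESeq2 recovered 86.9%, 63.7% and 25.9%, with a mean of 27.0 false calls among 144. Over the real genes the median standard error of the log2 fold change was 0.21 in limma-trend, with a 10th to 90th percentile range of 0.13 to 0.56. Before averaging, every pair of samples was compared by a chi-square test over genes with at least 50 reads in all. The statistic per degree of freedom was at least 14.9 for every pair, so no pair differed only by the sampling of reads from the same library. This does not exclude separate libraries made from the same RNA or animal.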

Results

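Histone deacetylase 7 (HDAC7) is a class IIa deacetylase that acts in transcriptional repressor complexes. The series asked what its loss changes in germinal center B cells, the antigen-activated B cells that proliferate and mutate their antibody genes in lymphoid follicles. Gene expression was measured by RNA sequencing in sorted splenic germinal center B cells from 4 Hdac7-deficient samples (KO) and 3 control samples (WT). The number of reads assigned to genes was 14681494 in KO1, 17787312 in KO2, 18642230 in KO3, 17340844 in KO4, 16399447 in WT1, 15149063 in WT2 and 18255012 in WT4. Between 18025 genes (WT1) and 19104 genes (WT4) had at least 1 read. The 10 most abundant genes took between 6.64% of the reads in KO1 and 9.92% in WT2.

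The samples were similar over the 14255 genes tested, and genotype was not the main axis of variation. The correlation of log2 values across genes, which are not independent replicates, had a median of 0.972 over the 6 pairs of KO samples, 0.957 over the 3 pairs of WT samples and 0.963 over the 12 pairs of a KO and a WT sample. WT1 stood apart from the rest, with correlations of 0.949 to 0.958 to the other 6 samples, whereas WT2 and WT4 correlated at 0.969. The leading principal component held 26.4% of the variance and placed WT1 at -67.3, against -3.0 to 33.1 for the other samples. The next component held 21.6% and ran from 42.8 in KO1 to -41.7 in WT2. On it KO1, KO2 and KO4 had positive scores, and KO3, at -11.1, lay below WT1, at -4.1.

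**Figure D1:**
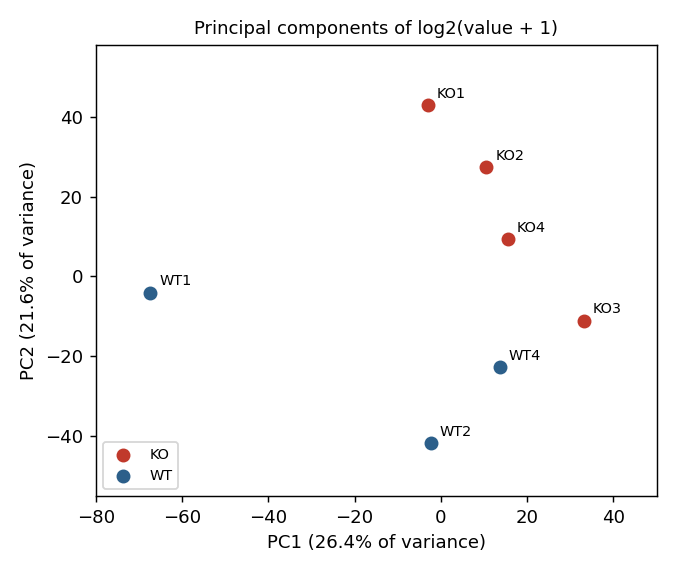
Scores of the 7 samples on principal components 1 (x axis, 26.4% of variance) and 2 (y axis, 21.6% of variance) of log2(value + 1) over the tested genes, each point a sample, KO in red and WT in blue. WT1 lies at -67.3 on the x axis, apart from the other 6 samples.

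The main comparison asked which genes differ between Hdac7-deficient and control cells. In the limma-trend test, 12 of 14255 genes passed an adjusted p of 0.05, of which 8 were higher and 4 were lower in KO. Limma without the mean-variance trend called 0 genes, with 1596 at an unadjusted p under 0.05 against 1724 for limma-trend, and the trend was chosen after both counts were seen. Limma-trend without KO2 called 3 genes. The KO and WT samples did not overlap for any of the 12, which was close to fixed by their selection on the same samples. Over all tested genes, KO and WT samples did not overlap for 1671 (11.7%), where independent samples give 5.71% by chance. The other splits of the same samples, which mix the genotypes, gave a median of 711.5 genes and at most 1588. The 8 higher genes rose by 0.72 to 4.03 on the log2 scale, and 6 of them more than doubled. The 4 lower genes had log2 fold changes of -1.65 to -0.74, and for 3 of them the KO level was less than 50% of the WT level. The files pair no identifier with a symbol, so neither Hdac7 itself nor any pathway or cell type marker was analysed here.

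The gene with the smallest p, MGP_C57BL6NJ_G0035579, rose 3.20-fold in KO. Its normalised read count was 1174 ± 186 (SD, n = 4) in KO and 363 ± 15.4 (SD, n = 3) in WT, a log2 fold change of 1.68 with a standard error of 0.15 and a limma adjusted p of 0.0019. MGP_C57BL6NJ_G0020071 rose 2.34-fold, from 1192 ± 112 (SD, n = 3) in WT to 2786 ± 201 (SD, n = 4) in KO, with a log2 fold change of 1.23, a standard error of 0.12 and a limma adjusted p of 0.0019. Among the lower genes, MGP_C57BL6NJ_G0032239 stood at 2312 ± 49.8 (SD, n = 4) in KO and 5335 ± 680.2 (SD, n = 3) in WT, a log2 fold change of -1.20 with a standard error of 0.11 and a limma adjusted p of 0.0019. MGP_C57BL6NJ_G0022670 stood at 119 ± 33.4 (SD, n = 4) in KO and 367 ± 51.2 (SD, n = 3) in WT, a log2 fold change of -1.65 with a standard error of 0.23 and a limma adjusted p of 0.030. Without the mean-variance trend none of these 4 genes passed, with limma adjusted p of 0.074 for the 3 genes given before the last and 0.17 for the last. The call for the last gene was also lost when KO2, KO4, WT1, WT2 or WT4 was left out, with limma adjusted p of 0.15, 0.098, 0.059, 0.14 and 0.077.

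**Figure D2:**
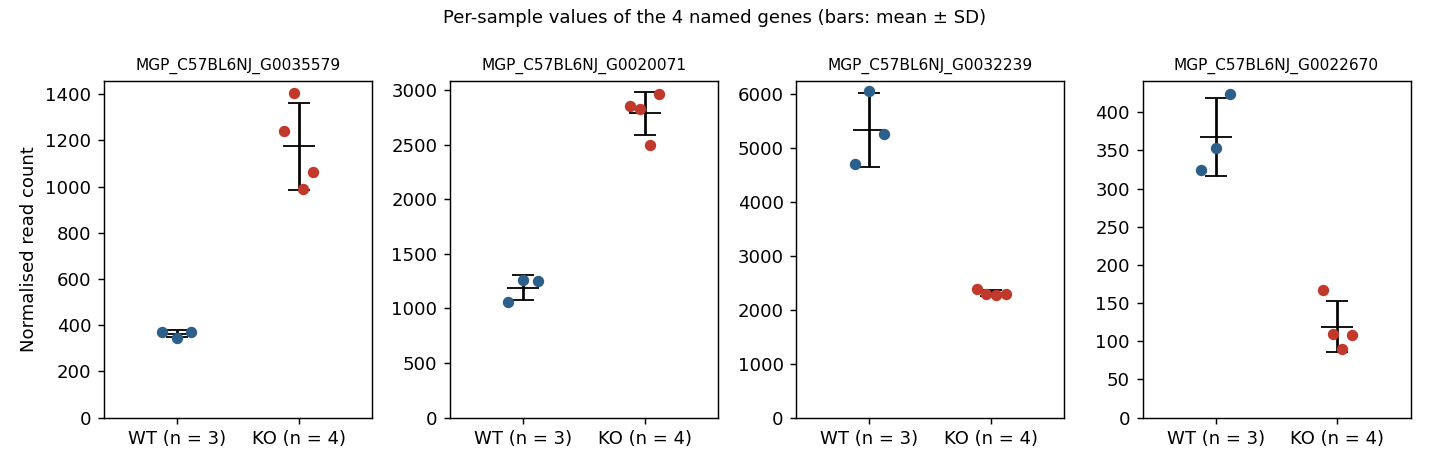
Normalised read count (y axis, from 0) of the 4 named genes in the 3 WT samples (blue) and the 4 KO samples (red), with each point a sample and bars giving the mean ± SD. In each gene all KO samples lie on the same side of all WT samples, as the naming rule required.

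The gene with the largest rise among the 12 was barely detected in WT. Its normalised read count was 74.6 ± 42.5 (SD, n = 4) in KO and 3.69 ± 2.98 (SD, n = 3) in WT, a log2 fold change of 4.03 with a 95% interval of 2.69 to 5.37 and a limma adjusted p of 0.041, and edgeR did not call it (adjusted p of 0.059). A further gene rose from 42.8 ± 26.5 (SD, n = 3) in WT to 327 ± 63.0 (SD, n = 4) in KO, a log2 fold change of 3.04 with a 95% interval of 2.30 to 3.79. The most abundant of the 12 rose from 6385 ± 1108 (SD, n = 3) to 12278 ± 930.4 (SD, n = 4), a log2 fold change of 0.95. These 3 genes were picked after their values were seen and are given without identifiers.

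For most genes the data bound the change from above. The median absolute log2 fold change was 0.21, and for 9842 genes (69.0% of those tested) the 95% interval of limma-trend lay between -1 and 1. For each such gene taken singly this excludes a 2-fold change on this scale in either direction. The intervals are not adjusted for the number of genes, so some of the 9842 may still change 2-fold. No gene had at least 10 reads in every KO sample and at most 3 in every WT sample. This depends on the cut-off: the gene with the largest rise had a normalised read count of 6.83 in WT1 and at least 31.2 in KO. The reverse pattern occurred for 4 genes, with 10 to 30 reads in each WT sample and totals of 3 to 7 reads over the 4 KO samples against 34 to 59 over the 3 WT samples. Of these, 3 were tested and none passed, with limma adjusted p of 0.14, 0.16 and 0.24. KO3, WT2 and WT4, a trio that mixes the genotypes, had 5 genes present in the trio alone by the same cut-offs. The 4 genes are therefore no evidence of a genotype effect.

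The authors' deposited table held a longer list. It gave an adjusted p under 0.05 for 274 genes, 160 higher and 114 lower in KO, among 13578 genes with an adjusted p. In the authors' deposited table the changes were mostly below 2-fold: 133 of the 160 higher genes and 78 of the 114 lower genes had an absolute log2 fold change under 1. The median was 0.58 for the higher and -0.83 for the lower genes. All 12 genes of the limma-trend test were among the 274 of the authors' deposited table. All 274 had the same direction and an unadjusted p under 0.05 in limma-trend, and KO and WT samples did not overlap for 267 of them (97.4%). These values were close to fixed by the selection of the 274 on the same reads of the same samples, and are no separate evidence for the list.

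**Figure D3:**
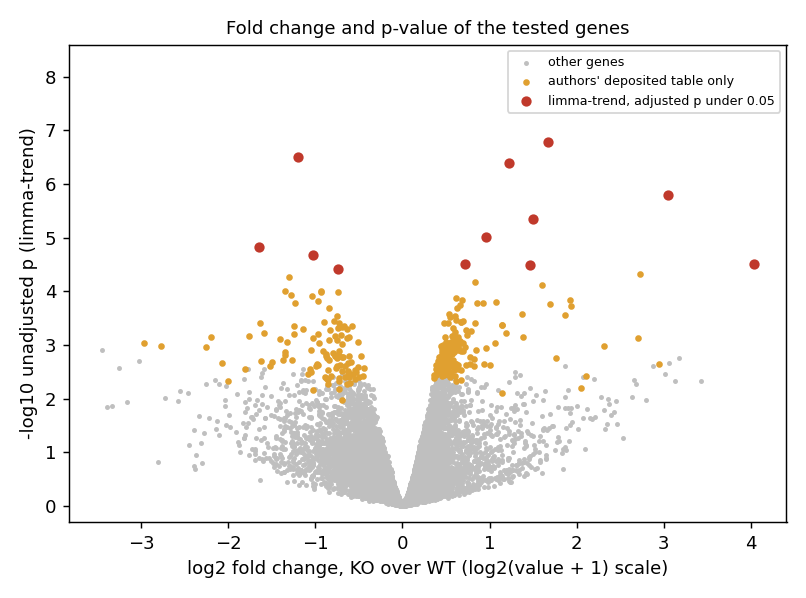
Log2 fold change of KO over WT (x axis, log2(value + 1) scale) against -log10 of the unadjusted limma-trend p (y axis) for the 14255 tested genes, each point a gene. The 12 genes past the adjusted threshold in limma-trend are red, and the other genes of the 274 called in the authors' deposited table are orange.

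The number of genes called therefore depended on the test. EdgeR's quasi-likelihood test on the recovered reads called 8 genes (5 higher, 3 lower), all of them among the 12, and limma-voom called 11, of which 10 were among the 12. Single samples also moved the counts. Limma-trend called 6 genes without KO1, 3 without KO2, 6 without KO4 and 7 without WT4. EdgeR called 3 without KO2, 16 without KO3, 4 without WT2 and 4 without WT4, and a DESeq2 refit called 74 without KO2, 181 without KO3, 105 without KO4 and 148 without WT2. Leaving out WT1, the sample that stood apart, gave 12 genes in limma-trend, of which 7 were among the original 12, and 310 in DESeq2, of which 162 were among the 274.

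**Figure D4:**
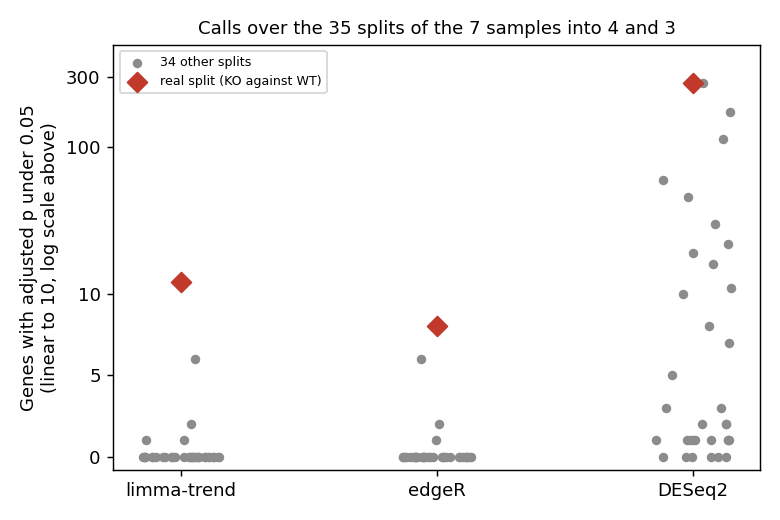
Number of genes with an adjusted p under 0.05 (y axis, linear to 10 and log above) in limma-trend, edgeR and DESeq2 for the real split into KO and WT (red diamond) and the 34 other splits of the 7 samples into 4 and 3 (grey points). The real split gave 12, 8 and 274 genes, and the highest other split gave 6, 6 and 273. The median over the other splits was 0, 0 and 2.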

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

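The simulation behind the DESeq2 count was run before its criterion was written down, and the term for KO3, WT2 and WT4 was added after the data were seen. Among 15 results checked for a KO sample lying apart from the other 3 there was 1 case, and chance gives about 5% of groups. It was MGP_C57BL6NJ_G0032239, where KO1 (2385) lay above the other KO samples (2279 to 2297), a gap of 0.834 of the range of the log2 values in a group with an SD of only 49.8.

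The authors' DESeq2 test called 274 genes and limma-trend 12. Of the 35 splits of the 7 samples into 4 and 3, only 1, the real split, gave as many as 12 limma-trend calls (highest other 6). That share is under 0.05, but chance is not excluded, because the trend was chosen after 12 calls with it and 0 without it were seen. Without KO2 the limma-trend count fell to 3, and in edgeR the real split gave 8 calls against 6 in the highest other. The real split was also the only 1 with as many as 274 DESeq2 calls. This rests on a single gene in a count that moved from 74 to 310 when each sample was left out. KO1, KO2 and WT1 against the rest gave 273, the highest of the other splits, although limma-trend and edgeR each called only 1 gene on that split. The median over the other splits was 2 DESeq2 calls. In data simulated without any change, false calls of the DESeq2 test at 4 against 3 samples reached at most 11, below the bound of 50% of the real count that had been set, but that bound was wrong because a split of the actual samples that mixes the genotypes gave far more DESeq2 calls than the simulated data. How many of the 274 are false therefore cannot be told apart from a broad, weak difference between the genotypes.

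WT1 stood apart in the principal components and held 73 genes with at least 10 reads there and at most 3 in every other sample, against 7 to 29 in the other libraries. A lower number of reads in WT1 is argued against: 2 libraries had fewer, and with every library thinned to 14681494 reads WT1 still held 65 such genes, against 10 to 19 elsewhere. After thinning WT1 also had the most genes absent in it alone (23 against 3 to 14) and the fewest genes detected (17904 against 18087 to 18802). The criterion written beforehand had asked that it not have the fewest, a part set aside after the result was seen because read totals were then equal, but thinning does not equalise the complexity of the libraries, and a less complex WT1 library stays open. Without WT1 the 12 genes kept a median of 103% of their log2 fold change, so their fold did not rest on WT1 alone. This does not decide whether WT1 set which genes were called. The 12 were chosen on all 7 samples, and kept a median of 95.4% to 104% whichever sample was left out. Without WT1, 7 of the 12 and 162 of the 274 DESeq2 calls stayed past the threshold. Leaving out another sample kept 3 (KO2) to 10 (KO3) of the 12, and 73 (KO2) to 187 (KO1) of the 274. The loss of calls was therefore not particular to WT1. Nothing tested shows what sets WT1 apart.

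In KO3, WT2 and WT4, 5 genes had at least 10 reads in each sample and at most 3 in every other sample, more than in any of the other 34 trios (highest 4, in the 3 WT samples). For 3 of them the other samples held 0 reads, against 57 to 79 in KO3 and 24 to 62 in WT2. Another of the 5 lay at the cut-offs, with 10 to 11 reads in the trio and up to 3 elsewhere. The lead over the other trios rests on that gene. No gene showed the reverse, with at most 3 reads in each sample of the trio and at least 10 in every other sample. A hidden division of the samples along this trio, which holds 2 of 3 WT but 1 of 4 KO samples, could have set the genotype calls. With the trio as a term, the 12 genes kept a median of 95.7% of their log2 fold change (lowest 85.4%) and 10 of them stayed past the threshold. This was close to fixed beforehand and does not decide the question, because KO and WT samples did not overlap for any of the 12. DESeq2 called 113 genes on the trio against the rest, and 316 genes by genotype with the trio as a term. What divides the samples, such as sex or litter, stays open and was not tested.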

How the results depend on the processing

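The limma-trend count stayed within 1.5 times of 12 under TMM and upper-quartile scaling, edgeR, limma-voom, both pseudocounts, both filters, a 2-fold minimum and the term for KO3, WT2 and WT4. It did not with DESeq2 (274), without the mean-variance trend (0, with 1596 genes at an unadjusted p under 0.05), or with KO1, KO2 and WT1 against the rest as a term (40, including all 12). Leaving out each sample gave 3 to 15 genes. The DESeq2 count of 274 became 63 with an absolute log2 fold change over 1, 426 with the KO1, KO2 and WT1 term, and 74 to 310 when each sample was left out. Both terms, the trend setting, TMM scaling before limma and the settings of DESeq2 were chosen after seeing the data. EdgeR with TMM, which the plan held for raw counts, was run as an added alternative. The cause of these changes was not tested. With the title number as a replicate block over the 6 samples numbered 1, 2 and 4, limma-trend called 60 genes and DESeq2 187. In limma-trend 25 of the 60 were higher and 35 lower in KO. The same samples without the block (the fit without KO3) gave 15 genes in limma-trend, 8 higher and 7 lower, so the balance of directions also moved. The samples share only a number: deviations from the group means correlated at 0.17, -0.06 and -0.10 for numbers 1, 2 and 4, and of these 6 samples only KO1 and WT1 correlated best with their own number. Of 84 values for the 4 named genes under 21 distinct alternatives, none changed direction and 9 lost the threshold: 4 without the trend, and 5 for MGP_C57BL6NJ_G0022670 when a sample was left out. The constant direction was close to fixed beforehand, because the naming rule asked for no overlap between KO and WT samples. Depth limits the genes with few reads, and the simulated recovery of 11.4% for 1.5-fold changes means that such changes are mostly missed by limma-trend. Leaving out immunoglobulin genes and the tests of gene lists and isotypes were not run, since the genes carry no names here.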

Other observations

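The terms for divisions of the samples and the count of consecutive identifiers were tests chosen after the data were seen. Single libraries held a few very high genes. A gene had 5092 reads in WT4 and at most 11 in any other library, and another had 652 in WT4 and at most 3 elsewhere. A further gene had 24145 reads in KO3 (0.130% of the library), against 233 to 716 in the other 6. Adding KO1, KO2 and WT1 against the rest as a term, a division picked from the data, moved the genotype calls to 40 in limma-trend, with all 12 kept, and to 426 in DESeq2, of which 259 were among the 274.

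Changed genes lay next to each other in identifier number more often than chance gives. Among the 274 genes of the authors' deposited table, 12 pairs had consecutive numbers, against a mean of 3.93 over 10000 random draws of genes of like expression (permutation p = 0.000500, one-sided), and 11 of the 12 pairs moved the same way. Some pairs shared a gene within longer runs of consecutive numbers, so the 12 pairs are not 12 separate cases. The excess of pairs was noticed in the data and then tested on them. Whether consecutive numbers mark neighbouring genes is not given in the sources used here. As a hypothesis, members of a pair may share reads or regulation whatever the genotype. The test of this was written down before it was run: within-group deviations of the pairs correlated at a median of 0.17, against 0.01 for random sets of called genes far apart in number. Of those sets, 80.6% fell below the value of the pairs, and their 95th percentile was 0.31, so the test decides neither way.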
